A study of Homo sapiens with 12 samples.

How the data were processed

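Polyadenylated RNA from MDA-MB-231 cells and derivatives was extracted with the RNeasy Mini Kit, purified with the Dynabeads mRNA DIRECT kit and made into libraries with the Ion Total RNA-Seq Kit v2, per the labels' protocols. Growth in DMEM with fetal bovine serum is given in the labels for the OCT-2 and GFP cells. TopHat2 2.0.8 and Cufflinks are named, with the build hg38, per the submitters' processing notes; the Cufflinks version is not given in the sources used here. The deposited values are FPKM, per the file headers, in 2 tables of 26372 rows each, one with 4 conditions and one with the OCT-2 and GFP cells. Each table has, per the file headers, 1 FPKM, a lower bound, an upper bound and a status for each group. The labels list 2 samples per group, so each column is taken as the authors' pooled value. How replicates were combined, the strand setting and the confidence level of the bounds are not given in the sources used here. Without a stated strand setting, reads of overlapping antisense genes cannot be told apart. Where values of both tables stand in one sentence they were normalized separately.

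Columns were mapped to groups by the names in the labels, with 0 value columns left unmapped. Gene loci from the tables were checked against the RefSeq annotation of GRCh38.p14: of 23620 symbols matched, 98.9% overlapped the annotated locus. FPKM columns summed to between 557151 in untreated 231Pa and 661478 in OCT-2 cells. The 10 highest genes took from 8.76% of the sum in untreated 231Pa to 11.6% in OCT-2 cells. Between 61 and 82 values per column lay outside their own interval, and 9 lower bounds per column were a placeholder. Library sizes were estimated from the spacing of low FPKM of single-transcript genes, since 1 read in a gene of known length fixes the unit. This is an estimate of the depth behind each column of the table of 4 conditions, and it was not used for the OCT-2 and GFP columns. Precision was taken from the deposited bounds, which are the authors' own.

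The comparisons were MDA-231-D against 231Pa without and with TGF-beta, TGF-beta against none in each line, and OCT-2 against GFP cells. A gene was eligible when both statuses were OK, the higher FPKM was at least 1 and its name was not that of a small RNA. Folds are log2 of the ratio of FPKM + 1. A call needed a 2-fold difference on that scale and deposited intervals that did not overlap. Because only pooled values were at hand, no test across replicates, no fit with a replicate block and no leaving out of samples was possible. Agreement between comparisons was counted as calls in both, beside n1 × n2 / N.

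For each of 33 gene lists, the median log2 fold of eligible members was set against 10000 random lists of the same size matched on expression in 10 bins, with seed 1; a list stands apart when its median lies outside the central 95%. Lists with fewer than 3 eligible members have no median. Some lists share members. Random lists describe these columns and are not a test across replicates.

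Genes were named by a rule fixed, like the lists, the comparisons and all but 1 alternative, before the data were examined. It takes POU2F2 and the other measured POU2 genes. For each comparison it takes the 6 called genes with the highest and the 6 with the lowest log2 fold that have 1 symbol and no LOC, LINC, clone-type or antisense name. It takes up to 4 eligible members of largest absolute log2 fold of each list described that has a called member or stands apart. For agreement it takes up to 6 genes per direction called in both comparisons by the smaller of both absolute folds, and all called in opposite directions if 5 or fewer. It takes the 4 largest differences of TGF-beta response in each direction among genes called in at least 1 line. Some genes that this rule names are not reported here. Where a symbol has several rows, the row with the highest mean FPKM was used. The values of C3 without TGF-beta and with OCT-2, of CXCL8 in GFP cells, and of IL1B with OCT-2 in the plot of levels, and the genes first named in the closing section, were chosen after their values were seen.

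Alternatives were pseudocounts of 0.1 and 5, no filter or a minimum FPKM of 5, any status, small RNA names kept, scaling of each column to its sum as in TPM, centring on the median, thresholds of 1.5-fold and 4-fold, fold alone, a lowest fold of the intervals over 1.5, and random lists from all eligible genes. After the data were seen, 1 was added that asks each interval to hold its own FPKM. Scaling to column sums shifts the log2 ratio of FPKM by -0.14 for MDA-231-D over 231Pa without TGF-beta and by -0.11 with it. The pseudocount weighs differently on the scaled values, so folds of genes with low FPKM move by other amounts.

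The steps were tested on simulated data with known answers, in which 200 genes were changed. Noise of the observed spread was drawn as normal, with its size from the median absolute log2 fold at like FPKM, so it held no outlying genes. With interval noise, 2-fold differences were recovered in 16.4% of cases for the clone comparison without TGF-beta (11779 genes), in 14.9% for TGF-beta in 231Pa (11700.0 genes) and in 41.8% for OCT-2 (11417 genes). With noise of the size of the observed spread, 2-fold differences were recovered in 5.97% of cases for the clone comparison without TGF-beta (12110 genes), in 0% for TGF-beta in 231Pa (11701 genes) and in 23.9% for OCT-2 (11625 genes). With interval noise, differences of 8-fold were recovered in 98.5%, 92.4% and 98.5% of cases in the same order. Of 100 lists without a planted difference, from 2 to 10 stood apart over the comparisons and both kinds of noise, with 10 for the clone comparison without TGF-beta and interval noise. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.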

Results

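Polyadenylated RNA was sequenced from MDA-MB-231, an established triple-negative breast cancer cell line, in 12 samples of 6 groups with 2 samples each. The parental line, here 231Pa, carried no transgene. Its highly metastatic clone, MDA-231-D, carried luciferase, so clone and transgene could not be separated. Both lines were sampled without and with transforming growth factor beta (TGF-beta), a cytokine that drives matrix production and epithelial plasticity in carcinoma cells. In the other part of the study, 231Pa cells carrying luciferase expressed either OCT-2, an octamer-binding POU-domain transcription factor best known in B cells and encoded by POU2F2, or green fluorescent protein (GFP) as the control. The authors' tables held 1 pooled FPKM per gene and group (fragments per kilobase of transcript, scaled to sequencing depth), with a lower and an upper bound. No difference below therefore has a replicate check, and no p-value is given. A gene was called higher or lower when log2 of the ratio of FPKM + 1 was at least 1 in size and the deposited intervals of both groups did not overlap. Log2 folds on this scale understate the difference of genes with low FPKM.

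The table of 4 conditions and the OCT-2 and GFP table were normalized separately, so each of the 5 comparisons was made within a table. FPKM of at least 1 were listed for 11509 genes in untreated 231Pa, 11466 in 231Pa with TGF-beta, 11272 in untreated MDA-231-D and 11348 in MDA-231-D with TGF-beta, against 11078 in OCT-2 cells and 11131 in GFP cells. Depth estimated from the spacing of low FPKM was 38.1 M reads for untreated 231Pa, 28.8 M for 231Pa with TGF-beta, 23.4 M for untreated MDA-231-D and 25.1 M for MDA-231-D with TGF-beta. For OCT-2 and GFP cells the low values did not lie on 1 step, with a next peak at 82.8% of the main peak, so the depth of those columns is unknown. For genes of 10 to 100 FPKM the deposited intervals reached about 51.0% below the value in untreated 231Pa and 32.1% below it in GFP cells. Intervals cleared each other at ratios of about 3.08 in untreated 231Pa and 1.94 in GFP cells, so counts of calls were not comparable between the tables.

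POU2F2, the OCT-2 gene (hg38 chromosome 19, 42086110 to 42132473, minus strand, protein coding), was low in the parental line and high in the metastatic clone. The authors' values were 2.03 FPKM in untreated 231Pa (deposited interval 0.501 to 3.56) and 56.5 FPKM in untreated MDA-231-D (23.1 to 90.3), a log2 fold of 4.25. With TGF-beta the values were 2.04 FPKM in 231Pa (0.417 to 3.66) and 46.8 FPKM in MDA-231-D (19.1 to 74.7), a log2 fold of 3.98 between the lines. TGF-beta gave no call for POU2F2 in 231Pa (log2 fold 0.00) or MDA-231-D (log2 fold -0.27). In the separately normalized second table POU2F2 stood at 67.5 FPKM in OCT-2 cells (46.5 to 88.5) and 8.18 FPKM in GFP cells (4.70 to 11.7), a log2 fold of 2.90. The share of these reads that came from the introduced OCT-2 sequence was not separable. Other octamer genes were near the floor in every group. POU2F1 lay between 0.301 and 0.769 FPKM, POU2F3 at no more than 0.195 FPKM and POU2AF1, a B-cell coactivator of OCT-2, at no more than 0.0620 FPKM.

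**Figure D1:**
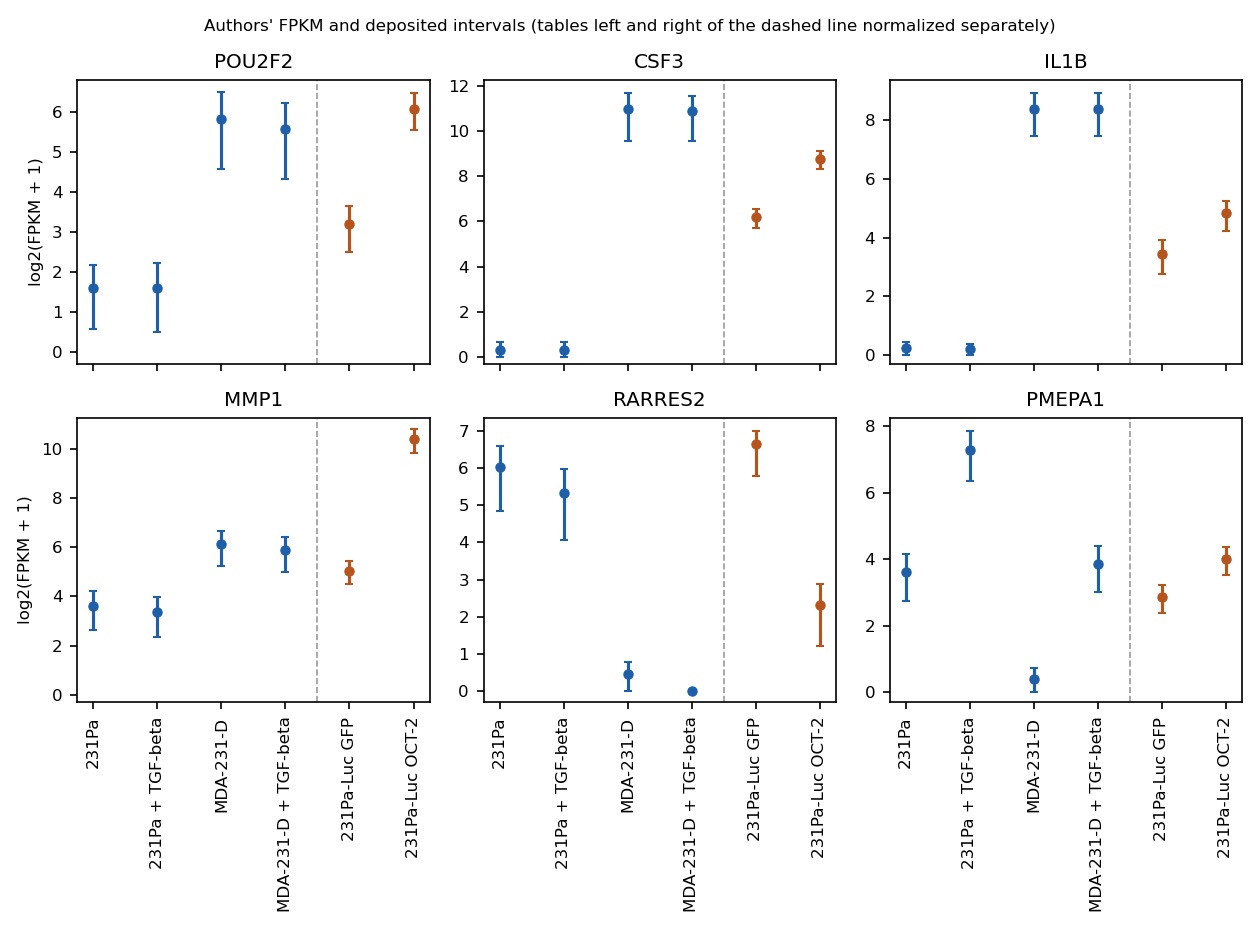
Log2(FPKM + 1) of POU2F2, CSF3, IL1B, MMP1, RARRES2 and PMEPA1 (y axes) in the 6 groups (x axes); points are the authors' pooled values, bars the deposited intervals, and the dashed line parts the 2 separately normalized tables. POU2F2 lies at 2.03 FPKM in 231Pa and 56.5 FPKM in MDA-231-D, and MMP1 at 31.9 FPKM in GFP cells and 1382 FPKM in OCT-2 cells.

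The first comparison asked how the highly metastatic clone differs from its parent without TGF-beta. MDA-231-D cells had high levels of inflammatory cytokine transcripts that were near the floor in 231Pa. CSF3, the granulocyte colony-stimulating factor gene (chromosome 17, 40015361 to 40017813, plus strand), stood at 1998 FPKM in MDA-231-D (759 to 3238) and 0.247 FPKM in 231Pa (0 to 0.602), a log2 fold of 10.65. CXCL1, a neutrophil-attracting chemokine, was at 626 FPKM in MDA-231-D (309 to 942) and 0.353 FPKM in 231Pa, a log2 fold of 8.86. IL1B, a fever-inducing cytokine, was at 335 FPKM (177 to 488) and 0.188 FPKM, a log2 fold of 8.14. Further chemokines followed, CXCL3 with a log2 fold of 7.42 and CXCL8 with 7.33, as did LCP1, a leukocyte actin-bundling protein, at 216 FPKM (112 to 320) in MDA-231-D and 0.979 FPKM in 231Pa. Lower in MDA-231-D were IFI27, an interferon-induced gene, at 0.212 FPKM (0 to 0.705) against 132 FPKM (62.3 to 202), and S100A4, a calcium-binding protein tied to motility, at 29.001 FPKM (7.05 to 50.8) against 2511 FPKM (953 to 3408). The cystatins CST4 and CST1 were listed at 0 in MDA-231-D and at 91.8 and 87.6 FPKM in 231Pa, with the caution that these genes are alike in sequence and can share reads. CLIC3, a chloride channel family member, had a log2 fold of -5.64 and RARRES2, the gene of the chemoattractant chemerin, one of -5.56.

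Of 11987 eligible genes, 254 were called higher and 467 lower in MDA-231-D, 6.01% of the total. Of 29 gene lists with a median, 6 stood above and 9 below random lists of the same size. The list of NF-kB and inflammatory cytokine genes stood farthest from random lists matched on expression. It had 21 members called higher, 0 lower and 5 not called, with a median log2 fold of 2.79 where the central 95% of random lists ran from -0.24 to 0.27. Members below 1 FPKM in 231Pa, CSF3, CXCL1 and IL1B among them, were eligible only through MDA-231-D. The filter therefore favours the higher direction in this count and median. A list of genes tied to bone and lung metastasis had 8 members called higher and 4 lower of 24, with a median of 0.73, which was inside the random range at an FPKM of at least 5. Among its members IL11, a bone-acting cytokine, was at 52.3 FPKM (26.5 to 78.4) in MDA-231-D and 5.86 FPKM in 231Pa. NEDD9, an adhesion scaffold, was the other way at 0.289 and 7.59 FPKM. MMP1, an interstitial collagenase, was at 68.7 FPKM (36.9 to 100.4) in MDA-231-D and 11.3 FPKM (5.22 to 17.5) in 231Pa. TGF-beta target genes had a median of 0.37, with 4 higher and 1 lower of 28. That median lay inside the random range with a pseudocount of 5 or an FPKM of at least 5. PMEPA1, a SMAD-induced feedback inhibitor of TGF-beta signaling on chromosome 20, in a locus the tables also give for NKILA, was the member called lower, at 0.319 FPKM (0 to 0.650) against 11.3 FPKM (5.68 to 16.9).

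Genes of antigen presentation and of luminal breast cells were lower in MDA-231-D. MHC class II, which presents extracellular peptides, had 7 of 8 eligible members called lower and a median of -2.25 (random range -0.65 to 0.45). Only 1 member was eligible in the TGF-beta comparison of MDA-231-D. Members below 1 FPKM in MDA-231-D were eligible only through 231Pa, so the filter favours the lower direction in this count and median. The HLA-DRA value was 0.413 FPKM in MDA-231-D and 28.5 FPKM in 231Pa, and CD74, the class II invariant chain, was at 22.2 FPKM (9.57 to 34.8) and 191 FPKM (102 to 281). HLA genes are similar in sequence and were read with that caution. MHC class I had 2 members called lower of 15 and a median of -0.72, and the type I interferon response list had 7 lower of 35 and a median of -0.58. BST2, which tethers budding viruses, stood at 1.84 FPKM against 71.4 FPKM. Luminal mammary markers had 7 of 14 called lower and a median of -1.79, with SPDEF, a luminal transcription factor, at 0.985 FPKM and 25.1 FPKM. The same limit of the filter applies to members such as SPDEF. Epithelial genes had 1 higher and 6 lower of 21 (median -0.74), among them KRT7, a simple-epithelium keratin, at 7.29 FPKM (2.82 to 11.7) against 371 FPKM (196 to 543). Mesenchymal genes were lower as well, with 0 higher and 6 lower of 22 and a median of -0.41, led by S100A4 and by CDH11, a mesenchymal cadherin, at 0.0555 FPKM and 22.7 FPKM. Integrins and adhesion receptors had 2 higher and 5 lower of 14 (median -0.78). ITGB4, the hemidesmosome integrin, was at 1.64 FPKM and 74.99 FPKM.

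Among metabolic and growth lists, cholesterol synthesis had a median of 0.55 with 1 member higher and 1 lower of 24. Hypoxia and glycolysis had a median of -0.34, with ADM higher (242 against 59.1 FPKM) and the glucose transporter gene SLC2A1 lower (64.3 against 261 FPKM). Medians of -0.49 for YAP-TEAD targets and 0.33 for cytosolic ribosomal proteins came with 0 called members each, and AP-1 and immediate early genes had a median of 0.32 with 2 higher of 22, inside the random range at an FPKM of at least 5. The 36 cell cycle genes gave 0 calls and a median of 0.15, inside the random range. Also inside it were matrix proteolysis (2 higher and 4 lower of 22, median -0.12), angiogenic factors (4 and 2 of 16, median 0.20), basal mammary markers (1 and 3 of 8, median -0.04) and chromatin regulators (median 0.03). At an FPKM of at least 5 the medians of matrix proteolysis (-0.45) and angiogenic factors (-0.98) lay outside it, the latter with the opposite sign. Of 26 B-lineage genes only 2 were eligible, as were 2 endothelial and 2 fibroblast markers, and 4 other blood-cell markers had a median of 0.12. Among genes left unchanged in the simulated data, 174 were called with interval noise and 28 with noise of the observed spread, against 721 in the data. The second kind of noise holds no outlying genes, so its 28 may understate calls without a difference. Luciferase was also carried by the GFP cells, in which CSF3 stood at 72.0 FPKM and CXCL8 at 286 FPKM in their separately normalized table. After the data were seen, 14 genes outside the cytokine list were added. They had at least 20 FPKM in the clone and at most 1 FPKM in its parent. Their excess in GFP cells over the parent, as a percentage of the clone level, had a median of 0.271% (quartiles -0.0324% to 1.59%). C3 and KYNU among them stood at 14.96% and 17.5%, and 8 cytokine genes chosen alike had a median of 7.32%. GFP cells, although they carried luciferase, thus stayed far below the clone for these 14 genes. The choice left out cytokine genes at 1 FPKM or more in the parent, some of which were near or above the clone level in GFP cells. CXCL8 was at 286 FPKM in GFP cells and 333 FPKM in the clone, and IL6 at 123 and 90.3 FPKM. Others were below it, such as IL24 at 10.3 and 42.4 FPKM.

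The same lines were then compared with TGF-beta present. The cytokine genes again led: CSF3 was at 1882 FPKM in MDA-231-D (749 to 3017) and 0.257 FPKM in 231Pa, CXCL1 at 559 and 0.814 FPKM, and IL1B at 333 and 0.149 FPKM. C3, the central complement component, was at 148 FPKM (77.1 to 219) in MDA-231-D and 0.452 FPKM in 231Pa, a log2 fold of 6.68. On the lower side were IFI27 (0.611 against 169 FPKM), S100A4 (22.5 against 1295 FPKM), CDH11 (0.141 against 47.1 FPKM), ITGB4 (1.31 against 90.1 FPKM), and CST1 and RARRES2, both listed at 0 in MDA-231-D and at 90.4 and 38.9 FPKM in 231Pa. Calls numbered 264 higher and 392 lower of 11970 eligible genes, or 5.48%.

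Among the lists, NF-kB and inflammatory cytokine genes had 19 higher and 0 lower of 25 (median 2.95) and metastasis genes 10 higher and 4 lower of 25 (median 0.72). As without TGF-beta, list members below 1 FPKM in 1 line were eligible only through the other, which favours differences in these counts and medians. MMP9, a gelatinase that opens basement membranes, stood at 25.8 FPKM (13.5 to 38.1) in MDA-231-D and 0.212 FPKM in 231Pa, within a matrix proteolysis list of median -0.31 (3 higher and 4 lower of 23). Mesenchymal genes had 10 of 22 called lower and a median of -1.25. Their members included LOX, a collagen cross-linking enzyme, at 1.03 and 24.7 FPKM, and COL5A1, a fibrillar collagen gene, at 6.15 and 61.4 FPKM. Fibroblast markers had 3 lower of 4 (median -1.52). KRT7 (29.3 against 823 FPKM) and KRT19 (43.0 against 471 FPKM) led 4 epithelial members called lower of 19 (median -1.06), beside 1 called higher. Luminal markers had 5 lower of 12 (median -1.11), integrins and adhesion receptors 2 higher and 6 lower of 15 (median -1.06), MHC class II 3 lower of 6 (median -2.005) and the interferon list 5 lower of 34 (median -0.55). TGF-beta target genes had a median of -0.27 with 3 higher and 2 lower of 28. PMEPA1 was at 13.6 FPKM (6.98 to 20.2) in MDA-231-D and 155 FPKM (80.8 to 229) in 231Pa, while WNT5A, a secreted Wnt ligand, was at 9.44 and 0.0324 FPKM. TGF-beta pathway components had a median of -0.84 although the 2 called members, INHBA (25.2 against 1.34 FPKM) and ENG, were higher. Cholesterol synthesis had a median of 0.77 (MVD 75.6 against 20.2 FPKM), cytosolic ribosomal proteins one of 0.55 with 0 calls, and BMP-SMAD targets one of 0.81 with ID3 called higher at 18.04 against 4.29 FPKM. The BMP-SMAD median was inside the random range under 3 other settings. Without TGF-beta it was -0.77, inside the random range and outside it under 3 other settings, and the difference between the treatments was not tested. Also inside the random range was the median of matrix proteolysis with no filter on low values. MHC class I (-0.37), YAP-TEAD targets (-0.36), hypoxia and glycolysis (-0.28) and unfolded protein response genes (0.31, inside the random range with a pseudocount of 5) also stood apart. Angiogenic factors had a median of 0.49 with 5 higher and 3 lower of 16, which was -0.01 with no filter on low values and -0.29 at an FPKM of at least 5. Genes left unchanged in the simulated data gave 175 calls with interval noise and 18 with noise of the observed spread, against 656 in the data. The 18 again come from noise without outlying genes.

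Across the 11657 genes eligible in both, the 2 clone comparisons had a Pearson r of 0.84 and a Spearman rho of 0.74, a correlation across genes, which are not independent replicates. In both, 193 genes were called higher and 283 lower, against 5.04 and 13.3 for independent calls, and 0 were called in opposite directions.

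**Figure D2:**
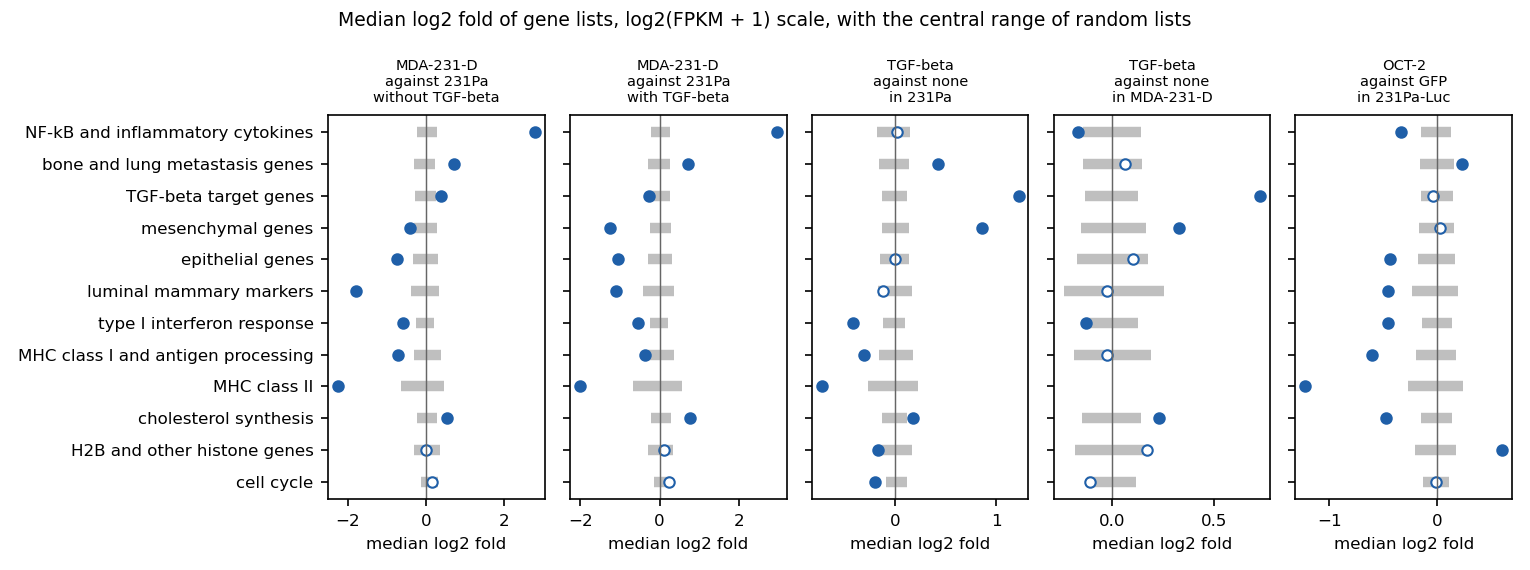
Median log2 fold (x axes, log2(FPKM + 1) scale, with a different range in each panel) of 12 gene lists (rows) in the 5 comparisons; grey bars are the central 95% of 10000 random lists matched on expression, and filled points lie outside them. NF-kB and inflammatory cytokine genes lie at 2.79 and 2.95 for MDA-231-D over 231Pa but at -0.33 for OCT-2 over GFP cells; MHC class II has no point for TGF-beta in MDA-231-D because fewer than 3 members were eligible.

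The comparison of treated with untreated parental cells addressed the response to the cytokine apart from any difference between the lines. Its dose and duration are not given in the sources used here. PMEPA1, the feedback inhibitor of TGF-beta signaling, was among the genes with the highest folds, at 155 FPKM with TGF-beta (80.8 to 229) and 11.3 FPKM without (5.68 to 16.9), a log2 fold of 3.66. Also called higher were C4orf26, an enamel matrix protein gene, at 12.5 and 0.247 FPKM, TAGLN, an actin-binding smooth muscle protein, at 36.3 and 2.84 FPKM, and TGFBI, a secreted matrix protein, at 250.3 FPKM (132 to 369) and 28.6 FPKM. Called lower were ID3, an inhibitor of differentiation and BMP target, at 4.29 FPKM (1.23 to 7.38) against 39.1 FPKM (19.1 to 59.0), a log2 fold of -2.92, and AGR2, a luminal disulfide isomerase, at 0.495 against 10.0 FPKM. VIPR1 (log2 fold -2.61), PLEKHG4 (-2.37) and CD22, a B-cell lectin (1.31 against 10.5 FPKM, log2 fold -2.32), were also called lower. H3F3A, a histone H3.3 gene with many processed copies, was listed at 0 with TGF-beta and at 32.0 FPKM (2.38 to 64.1) without, a value to be read with caution.

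Calls covered 69 genes higher and 39 lower of 11695, or 0.923%. TGF-beta target genes had 8 higher and 0 lower of 27, with a median of 1.22 (random range -0.13 to 0.12). Mesenchymal genes had 7 higher and 0 lower of 22 (median 0.86), including COL1A1 at 15.6 against 1.30 FPKM, COL6A3 at 28.8 against 3.52 FPKM and the fibronectin gene FN1 at 153 FPKM (67.5 to 238) against 35.3 FPKM. Fibroblast markers had 3 higher of 4, the collagen genes COL1A1 and COL1A2 and the surface protease gene FAP, with a median of 1.70. Basal mammary markers had 2 higher of 8 (median 0.58), KRT17 among them, and the metastasis list had 2 higher and 1 lower of 18 (median 0.42). Integrins and adhesion receptors (median 0.50, ITGB1 362 against 142 FPKM), angiogenic factors (median 0.70, THBS1 342 against 107 FPKM), neural genes (median 0.45, inside the random range with no filter on low values) and cholesterol synthesis (median 0.18) stood above random lists with 0 calls each.

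Lower with TGF-beta stood the BMP-SMAD targets, with ID1 and ID3 called lower among 5 (median -0.67), and MHC class II, with its master regulator CIITA called lower at 0.239 against 2.14 FPKM (median -0.72). Interferon response genes (median -0.41), MHC class I (median -0.31) and cell cycle genes (median -0.20, AURKA 59.5 against 125 FPKM) were below random lists with 0 calls, and histone genes had a median of -0.17 that lay inside the random range under 4 other settings. Epithelial genes did not stand apart (2 lower of 20, median 0.00), although ELF3, an epithelial transcription factor, was at 0.132 against 2.29 FPKM. Neither did NF-kB and inflammatory cytokine genes, with a median of 0.03 and CSF1, the macrophage growth factor, called lower at 43.0 against 133 FPKM. Matrix proteolysis had 2 called higher, ADAM19 among them, and a median of 0.06, which was 0.48 and outside the random range at an FPKM of at least 5. Simulated noise of the width of the deposited intervals called 167 genes with no difference, more than the 108 in the data, and noise of the size of the observed spread called 0. The second kind of noise holds no outlying genes, so its 0 follows largely from how it was drawn.

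In the metastatic clone TGF-beta gave fewer calls, with 44 genes higher and 8 lower of 11537, or 0.451%, from columns with fewer estimated reads than those of 231Pa. PMEPA1 was at 13.6 FPKM (6.98 to 20.2) with TGF-beta and 0.319 FPKM (0 to 0.650) without, a log2 fold of 3.47. ANGPTL4, an inhibitor of lipoprotein lipase linked to lung metastasis, was at 71.7 FPKM (36.1 to 107) and 5.70 FPKM (1.65 to 9.78), a log2 fold of 3.44. ALOX5AP, which feeds leukotriene synthesis, was at 71.7 and 6.69 FPKM, C4orf26 at 18.7 and 1.21 FPKM, COL6A3 at 9.65 and 0.518 FPKM and ANXA8L1, which has a near-identical copy, at 9.30 and 0.493 FPKM. TGFBI (336 against 57.3 FPKM) was called higher here too. The genes called lower were led by TCEB2, the elongin B gene, at 438 FPKM (226 to 650.3) against 1932 FPKM (937 to 2929), a log2 fold of -2.14, and by IL24, a cytokine of the IL-10 family, at 9.10 against 42.4 FPKM, followed by ASB2 (-1.89), PTGES, a prostaglandin E synthase (-1.66), and IGFN1 (-1.47). HIST1H2BL, a histone gene, was listed at 0 with TGF-beta and at 1.45 FPKM without.

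TGF-beta target genes in MDA-231-D had 5 higher and 0 lower of 27 and a median of 0.73 (random range -0.13 to 0.13). Mesenchymal genes had 3 higher of 20 (median 0.33), angiogenic factors 3 higher of 16 (median 0.33, PDGFB 23.9 against 4.63 FPKM), matrix proteolysis 1 higher of 21 (median 0.30) and basal markers 1 higher of 7 (median 0.54). Above random lists with 0 calls were integrins and adhesion receptors (median 0.37), cholesterol synthesis (0.23), unfolded protein response genes (0.19), cytosolic ribosomal proteins (0.16) and 4 other blood-cell markers (0.80, LAPTM5 127 against 61.7 FPKM). Below them were BMP-SMAD targets (median -0.62, ID1 14.1 against 41.7 FPKM), AP-1 and immediate early genes (-0.22), NF-kB and inflammatory cytokine genes (-0.17, with IL24 called lower) and the interferon list (-0.12), which lay inside the random range under 3 other settings. With no filter on low values the medians of BMP-SMAD targets, AP-1 genes and blood-cell markers were inside the random range, as was that of unfolded protein response genes with a pseudocount of 5. Genes left unchanged in the simulated data gave 153 calls with interval noise, against 52 in the data. Noise of the observed spread gave 0, which again follows largely from how it was drawn.

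The lines shared part of their TGF-beta response. Of 10928 genes eligible in both, 105 were called in at least 1 line: 21 in both, all higher, 60 in 231Pa alone and 24 in MDA-231-D alone, against 0.218 expected to be called higher in both if calls were independent. Of the genes called higher in 231Pa, 58 of 58 had a positive log2 fold in MDA-231-D, and of those called lower, 18 of 23 had a negative one. Genes called higher in both with wide margins included PMEPA1, C4orf26, COL6A3, TGFBI and FSTL3, an activin-binding protein. Of 26 TGF-beta target genes, 20 had the smaller fold in MDA-231-D, with a median difference of -0.50. TAGLN had a log2 fold of 3.28 in 231Pa and 1.38 in MDA-231-D, and SEMA7A, a membrane-anchored semaphorin, 1.81 and 0.05. In the other direction, ANGPTL4 had 0.73 and 3.44, ALOX5AP 1.09 and 3.24, and OSTM1 -0.72 and 1.49. TCEB2 had 0.59 and -2.14. H3F3A was listed at 0 in treated 231Pa and stood at 50.7 FPKM in treated MDA-231-D. The deposited intervals left 0 of the 105 genes with a difference between lines that excluded 0, so no response was shown to differ. Each range joined the far ends of the intervals of both lines and both treatments, from -3.48 to 2.33 for TGFBI around -0.55. Only a very large difference could exclude 0 over such ranges, so this count could not decide whether responses differed. Across genes, the folds of both lines had r = 0.27 and rho = 0.13.

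**Figure D3:**
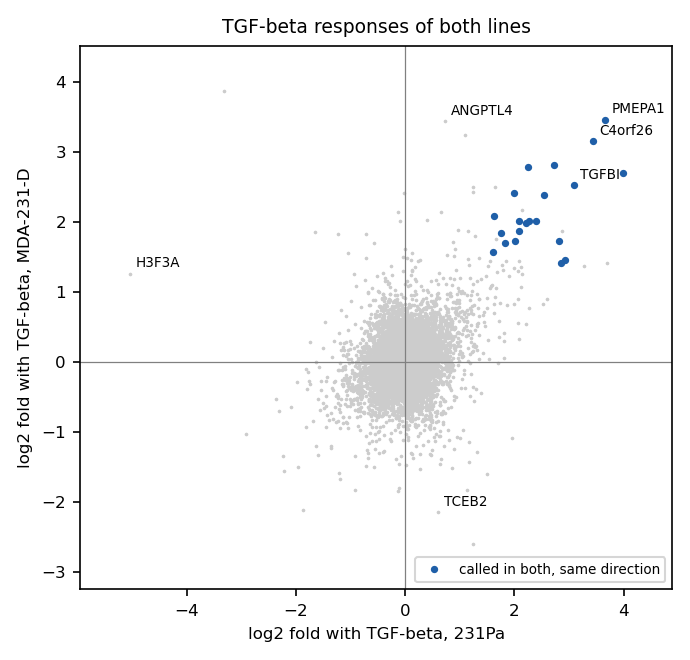
Log2 fold with TGF-beta in 231Pa (x axis) and in MDA-231-D (y axis), on the log2(FPKM + 1) scale; each point is a gene eligible in both lines, and blue points were called in both. The 21 blue points all lie in the upper right, with PMEPA1 at 3.66 and 3.47 and TGFBI at 3.09 and 2.53.

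The last comparison asked what OCT-2 does when it is introduced into parental cells. MMP1, on chromosome 11 in a locus the tables also give for MMP3 and WTAPP1, had the highest fold among called genes, at 1382 FPKM in OCT-2 cells (929 to 1832) and 31.9 FPKM in GFP cells (21.8 to 42.0), a ratio of 43.3 and a log2 fold of 5.39. GZMA, a cytotoxic lymphocyte protease, was at 17.1 FPKM (9.01 to 25.3) and 0.214 FPKM, TRPV4, a calcium channel, at 14.7 and 0.302 FPKM, ALDH3A1, an aldehyde dehydrogenase, at 13.9 and 0.869 FPKM, and KYNU, a kynurenine pathway enzyme, at 52.3 FPKM (36.8 to 67.8) and 6.67 FPKM. H3F3A was at 385 and 34.7 FPKM, again with the caution of its copies. On the lower side, LGALS12, a galectin (chromosome 11, 63506052 to 63516774), was at 0.117 FPKM (0 to 0.403) against 27.3 FPKM (18.6 to 36.0), a log2 fold of -4.66. RARRES2 (chromosome 7, 150338318 to 150341674, minus strand) was at 3.94 FPKM (1.32 to 6.39) against 99.2 FPKM (54.5 to 127), a log2 fold of -4.34. CLIC3 (2.13 against 48.8 FPKM), RARRES3, a retinoid-induced growth regulator (12.7 against 156 FPKM), SPINK4 (0.411 against 14.98 FPKM) and COL6A2 (2.16 against 28.9 FPKM) followed. In all, 95 genes were called higher and 230 lower of 11496, or 2.83%.

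Antigen presentation and interferon genes were lower in OCT-2 cells. MHC class II had 5 of 10 members called lower and a median of -1.22 (random range -0.27 to 0.24), with HLA-DRA at 61.2 FPKM (39.2 to 82.7) against 158 FPKM (103 to 207) and HLA-DPA1 at 18.4 against 74.1 FPKM. MHC class I had 3 lower of 15 (median -0.60), among them HLA-B at 109 FPKM (78.0 to 141) against 495 FPKM (355 to 636). Of 34 interferon response genes, 7 were called lower and 0 higher (median -0.46), including OASL at 3.56 against 35.5 FPKM, IFIT2 at 1.63 against 14.2 FPKM and the ubiquitin-like modifier gene ISG15 at 169 against 522 FPKM. The NF-kB and inflammatory cytokine list was split, with 4 members higher, 6 lower and 16 not called, and a median of -0.33. CSF3 was at 434 FPKM in OCT-2 cells (313 to 556) and 72.0 FPKM in GFP cells (51.0 to 93.1), and IL1A was called higher with a log2 fold of 1.98. CSF2, the granulocyte-macrophage factor gene, was at 79.6 FPKM (44.2 to 105) against 338 FPKM (195 to 423), and IL32 at 9.65 against 52.7 FPKM. In the GFP cells themselves, 19 of 26 genes of this list were higher than in untreated 231Pa by the same rule, across tables normalized separately.

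The metastasis list had 7 higher and 2 lower of 25 (median 0.24), with MMP1 leading, NEDD9 at 2.44 against 14.7 FPKM and CXCR4, a chemokine receptor, at 2.85 against 12.7 FPKM. Its median was -0.05 when genes had to reach an FPKM of 5. Matrix proteolysis had 3 higher and 1 lower of 21 with a median of 0.04. MMP3, a stromelysin, was at 50.4 FPKM in OCT-2 cells but with an interval from 0 to 142, and was not called. Histone genes had 4 higher of 14 and a median of 0.60, with HIST1H2AC at 438 against 153 FPKM and HIST1H1C at 1609 against 695 FPKM. Polyadenylated histone reads and family members alike in sequence make these values uncertain. Cholesterol synthesis had a median of -0.48 with 1 lower of 24, epithelial genes one of -0.44 with 0 calls, luminal markers one of -0.46 with 1 higher of 15, AP-1 and immediate early genes one of -0.23 with 3 lower of 26, and hypoxia and glycolysis one of -0.22 with 1 call each way, inside the random range at an FPKM of at least 5. YAP-TEAD targets (0.21), chromatin regulators (0.15) and 3 endothelial markers (0.66, with EGFL7 called lower at 7.96 against 40.6 FPKM) had medians above random lists, though that of the endothelial markers was -0.04 with no filter on low values. TGF-beta targets (3 higher and 1 lower of 25, median -0.04), mesenchymal genes (2 and 3 of 21, median 0.02) and cell cycle genes (median -0.01) did not stand apart. Among 5 eligible blood-cell markers, CD14, a monocyte receptor, was called higher at 233 against 73.8 FPKM, and 2 of 26 B-lineage genes were eligible. S100A4 was at 968 FPKM in OCT-2 cells, a value outside its own interval of 456 to 943, against 2539 FPKM in GFP cells. Among genes left unchanged in the simulated data, interval noise gave 63 calls and noise of the observed spread 6, against 325 in the data. The 6 come from noise without outlying genes.

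OCT-2 cells shared more calls with the metastatic clone than independent lists would. For MDA-231-D over 231Pa without TGF-beta, 22 genes were called higher in both (1.02 for independent calls) and 86 lower in both (7.91), across 11164 genes with r = 0.30 and rho = 0.21. The genes higher in both were led by CSF3, POU2F2, KYNU, IL1A, MMP1 and BCL2A1, a BCL2 family survival gene. POU2F2 is the introduced gene, so its call in OCT-2 cells was fixed by the design. Those lower in both were led by RARRES2, CLIC3, RARRES3, SPINK4, TP53I11 and CEMIP, a hyaluronan-binding protein. Another 13 genes were lower in OCT-2 cells and higher in MDA-231-D (2.88 for independent calls), and 4 were higher in OCT-2 cells and lower in MDA-231-D: TBXAS1, CST1, PMEPA1 and FAM84B. With TGF-beta present in the clone comparison the shared counts were 27 higher (1.01) and 74 lower (6.09) of 11086 genes, with 15 and 4 in opposite directions. GFP cells over untreated 231Pa, with no OCT-2 introduced, also shared calls with that comparison, with 47 higher in both (3.08 for independent calls) and 31 lower in both (3.53) of 11358 genes and r = 0.27. Overlap with the clone was therefore not particular to cells given OCT-2. POU2F2 was itself higher in GFP cells (8.18 FPKM, 4.70 to 11.7) than in untreated 231Pa (2.03 FPKM, 0.501 to 3.56), across separately normalized tables. A part of OCT-2 in the overlap of GFP cells with the clone was therefore neither shown nor excluded. The calls for OCT-2 cells are relative to GFP cells. Calls for TGF-beta were also set beside those for OCT-2. In 231Pa, 2 genes were higher in both, PMEPA1 and FN1 (0.268 for independent calls), and 6 lower in both, LGALS12, GPRC5C, TSPAN8, RCSD1, CX3CL1 and PPL (0.762), while 3 were higher with OCT-2 and lower with TGF-beta (H3F3A, ADGRF1 and SOCS3, 0.205 for independent calls) and 3 the other way (PCDH1, BHLHE40 and KRT17, 0.997). In MDA-231-D, PMEPA1 was the 1 gene higher in both (0.230), and IL24 and TCEB2 the 2 lower in both (0.0649), while the 3 genes SELM, NEDD9 and PPAPDC1A were lower with OCT-2 and higher with TGF-beta (0.441). All overlaps here are between tables normalized separately, and the correlations are across genes.

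**Figure D4:**
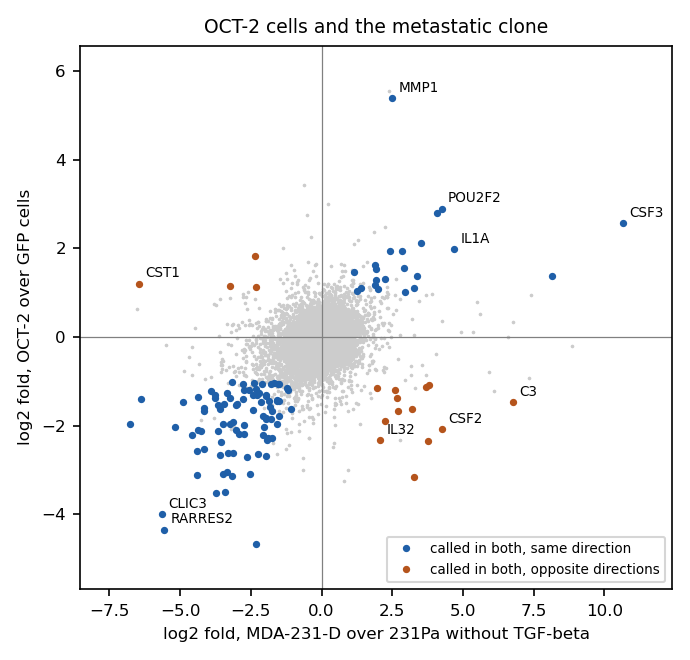
Log2 fold of OCT-2 over GFP cells (y axis) against that of MDA-231-D over 231Pa without TGF-beta (x axis), on the log2(FPKM + 1) scale; each point is a gene eligible in both comparisons, blue where called in the same direction and orange where called in opposite directions. CSF3 lies at 10.65 and 2.58, MMP1 at 2.50 and 5.39, and C3 at 6.77 and -1.46; CST1 is placed at its fold against a group listed at 0.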

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

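Of the tests here, the one on sequencing depth was fixed before its result was seen, and the others were chosen after. None of the opposite signs below was tested as a difference across replicates, because no values per replicate were at hand.

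Several results had opposite signs under the same contrast. The TGF-beta target list had a median log2 fold of 0.37 for MDA-231-D over 231Pa without TGF-beta and -0.27 with it, a difference that was not tested. The read-through gene TMEM189-UBE2V1 had -4.34 without and 2.85 with TGF-beta between the lines, and -3.31 in 231Pa and 3.88 in MDA-231-D between treatments, also not tested. It shares exons with TMEM189 and UBE2V1, so its value is uncertain. H3F3A had -5.04 with TGF-beta in 231Pa and 1.27 in MDA-231-D, not tested, with its FPKM listed at 0 in treated 231Pa. The difference of TGF-beta response between the lines was 7.19 for TMEM189-UBE2V1 and 6.31 for H3F3A, and the ranges that the deposited intervals allow, -0.997 to 10.21 and -0.55 to 12.5, both include 0.

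Cytokine genes were higher in the GFP control than in untransduced 231Pa, although both derive from the parental line. Between the separately normalized tables, 19 of 26 were called higher, with a median log2 of 2.07 where random lists ran from -0.43 to 0.04. CXCL8 was at 286 FPKM in GFP cells and 1.07 FPKM in 231Pa, and CSF3 at 72.0 and 0.247 FPKM. Members below 1 FPKM in 231Pa, CSF3 among them, were eligible only through GFP cells, so the filter favours the higher direction. An admixture of MDA-231-D cells is argued against, because the excess of GFP cells over 231Pa, as a percentage of the level in MDA-231-D, had a median of 0.271% for MDA-231-D genes outside the cytokine list (quartiles -0.0324% to 1.59%, 14 genes). The median was 7.32% for 8 cytokine genes chosen by the same levels, although C3 and KYNU outside the list stood at 14.96% and 17.5%. Those levels leave out cytokine genes at 1 FPKM or more in 231Pa, such as CXCL8, which was at 333 FPKM in MDA-231-D. Separate normalization as the whole cause is also argued against, since the list median lay 2.31 log2 above the median of all genes. The luciferase and GFP vectors, culture and library batch, which all differ between the tables, stay open, since 0 tables hold both groups, and a biological difference between the parental cultures likewise stays open and untested.

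Fewer genes were called for TGF-beta in MDA-231-D than in 231Pa, and the MDA-231-D columns rest on fewer reads. Among 3994 genes with a mean of at least 20 FPKM, where depth matters least, 116 reached 2-fold in 231Pa and 78 in MDA-231-D. The ratio was 1.49 (exact interval 1.11 to 2.01, with a bound of 1.2 set in advance). That interval takes genes as independent and both counts as separate, although they cover the same genes. It holds no spread between replicates. The interval holds the bound, so this count did not settle whether lower depth played a part. For genes of 10 to 100 FPKM, deposited intervals cleared each other at ratios of about 3.08 in both 231Pa columns and treated MDA-231-D. The ratio was 3.07 in untreated MDA-231-D. These near-equal widths argue against lower depth as the cause of fewer calls at those levels, while genes of lower FPKM were not covered. A weaker response of the clone stays possible and was not tested.

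Low values in the table of 4 conditions lie on 1 step per column. Averaging 2 libraries of unequal scale would put several steps in each column, but the next peak reached at most 5.63% of the main peak over the 6 pairs of columns, which argues against it. A single library, or reads merged before estimation, would also leave a low next peak. For these the 5.63% only restates the pattern and is no separate test. In the OCT-2 and GFP table the next peak stood at 82.8% of the main peak, which leaves open how those columns were made. No biological explanation was tested for this pattern.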

How the results depend on the processing

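The requirement that each interval hold its own FPKM was chosen after the data were seen, and the other settings before. It left every call count within 1.5 times. Of 130 recomputed call counts 44 moved by more than 1.5 times. With a pseudocount of 5, which shrinks folds of low genes by construction, calls higher and lower were 145 and 279 for MDA-231-D over 231Pa (254 and 467 as reported), 148 and 234 with TGF-beta (264 and 392), 40 and 101 for OCT-2 (95 and 230), 23 lower for TGF-beta in 231Pa (39) and 4 lower in MDA-231-D (8). At an FPKM of at least 5 they were 165 and 309, 161 and 258 with TGF-beta, and 4 lower for TGF-beta in MDA-231-D, by construction from fewer genes. Requiring 4-fold left 141 and 221, 145 and 180 with TGF-beta, 32 and 9 for TGF-beta in 231Pa, 23 and 2 in MDA-231-D, and 17 and 55 for OCT-2. Fold alone gave 670 and 1008, 643 and 896 with TGF-beta, 201 and 187 for TGF-beta in 231Pa, 152 and 93 in MDA-231-D, and 162 higher for OCT-2. A lowest fold over 1.5 left 138 and 209, 139 and 167 with TGF-beta, 25 and 8 for TGF-beta in 231Pa, 15 and 0 in MDA-231-D, and 32 and 93 for OCT-2. TPM scaling and any status each gave 15 lower for TGF-beta in MDA-231-D; the cause was not tested.

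Calls in both clone comparisons numbered 109 higher and 162 lower with a pseudocount of 5, and 119 and 182 at an FPKM of at least 5 (193 and 283 as reported). OCT-2 with the clone gave 11 and 38, then 14 and 52 (22 and 86); with TGF-beta 12 and 34, then 44 lower (27 and 74). OCT-2 with TGF-beta in 231Pa gave 0 and 1, then 2 lower (2 and 6), and in MDA-231-D 0 and 1 with the pseudocount (1 and 2). The median difference of TGF-beta targets was -0.38 with a pseudocount of 5 (-0.50 as reported). Of 1309 list medians 1262 kept their side of the random range, 25 came inside it and 18 left it, among them angiogenic factors without TGF-beta (-0.98 at an FPKM of 5, 0.20 as reported). Another 4 outside it as reported changed sign: angiogenic factors with TGF-beta (-0.0112 without a filter, -0.29 at an FPKM of 5), metastasis genes with OCT-2 (-0.0539 at an FPKM of 5) and endothelial markers with OCT-2 (-0.0379 without a filter). The cause was not tested. Of 4224 recomputed folds of named genes 202 moved beyond the reported interval, and 0 folds of called genes changed sign. Leaving out each replicate and a replicate block could not be run. No paired analysis was possible because no values per replicate were at hand. Depth limits low genes, since 1 read is a large step there.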

Other observations

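The 2 lists in this part, and every test on them, were chosen after the data had been seen. In MDA-231-D cells, several cancer-testis genes of the X chromosome, normally limited to germ cells, were higher than in 231Pa. Of 89 listed genes, 17 were eligible without TGF-beta, 13 called higher and 0 lower, and 19 with TGF-beta, 15 called higher and 0 lower. A gene low in 231Pa was eligible only if it reached 1 FPKM in MDA-231-D, so the filter favours this direction and no median is given for the clone. MAGEA3 was at 78.5 FPKM in MDA-231-D (42.0 to 115) and 0.0160 FPKM in 231Pa, MAGEB2 at 66.1 FPKM (35.1 to 96.9) and 0.0519 FPKM, MAGEC1 at 20.1 FPKM and 0.113 FPKM, and SSX1 at 46.9 FPKM and 0.334 FPKM. SPANXB1 was at 2145 FPKM (767 to 2472) and 51.0 FPKM. TGF-beta gave 0 calls among the 4 of these genes eligible in 231Pa and the 18 eligible in MDA-231-D. With 0.923% and 0.451% of all eligible genes called, 0 calls among so few says little about these families. In OCT-2 over GFP cells 0 of 8 were called, the median of 0.35 stood above random lists (-0.35 to 0.29), and SPANXB1 was at 77.2 FPKM against 71.3 FPKM in GFP cells. Members of these families are alike in sequence, so the level of a single member is uncertain.

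Complement and acute-phase genes, which liver and epithelia secrete in inflammation, had opposite directions in the clone over 231Pa and in OCT-2 over GFP cells. The tables were normalized separately and the difference was not tested. In MDA-231-D over 231Pa without TGF-beta, 6 of 11 were called higher and 0 lower (median 1.53), with C3 at 156 FPKM against 0.446 FPKM, SAA1 at 626 against 47.3 FPKM and LCN2, a siderophore-binding protein, at 20.03 against 1.18 FPKM. With TGF-beta in both lines the count was again 6 of 11 (median 1.59). C3, C1S and SAA4, and with TGF-beta also LCN2 (0.884 FPKM), were below 1 FPKM in 231Pa and eligible only through MDA-231-D. The filter therefore favours the higher direction in these counts and medians. In OCT-2 over GFP cells, 5 of 10 were called lower and 0 higher (median -1.27), with C3 at 7.996 FPKM (5.51 to 10.5) against 23.8 FPKM (17.1 to 30.5), CFB at 10.5 against 37.4 FPKM and LCN2 at 11.6 against 111 FPKM. These GFP values were themselves above those of untreated 231Pa in the other table (C3 0.446, CFB 5.55 and LCN2 1.18 FPKM). OCT-2 cells also stood above untreated 231Pa for these genes, so the lower direction is relative to a raised control. With TGF-beta the list stood below random lists in 231Pa, at a median of -0.60 (random range -0.26 to 0.22) with PTX3 called lower of 8 (8.92 against 34.1 FPKM), and in MDA-231-D, at -0.28 (random range -0.20 to 0.21) with 0 of 11 called. SAA1 and SAA2 are near-identical and share reads.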
